A study of Mus musculus with 24 samples.

How the data were processed

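Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was measured in mouse bone marrow-derived macrophages, which are macrophages grown in culture from bone marrow cells, of the FVB/Hsd strain at day 7 of differentiation. The cells carried a retroviral short hairpin against Wdr82 (shWdr82) or a control vector, and were left untreated or given lipopolysaccharide (LPS), a bacterial cell wall component that activates macrophages, at 10 ng/ml. WDR82 is a subunit of the SET1 histone H3 lysine 4 methyltransferase complexes and of a PNUTS phosphatase complex. The 24 libraries are 6 antibodies by 2 vectors by 2 treatments, with 1 library in each group. The antibodies were against H3K4me3, H3K27ac, H3K4me1, H3K36me3, total RNA polymerase II (Pol II) and Pol II phosphorylated at serine 2 of its C-terminal repeats (Ser2P). The control was an empty vector for H3K4me3 and H3K27ac and a scrambled hairpin for the other 4 antibodies. The sample titles give 4 h of LPS for H3K4me3 and H3K27ac and 45 min for the others, while the protocol text speaks of 4 h alone. Each antibody was therefore compared within its own 4 libraries, and no LPS effect was compared between antibodies as if the times matched.

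The values are peak lists, 1 per library. Reads were aligned with Bowtie 0.12.7 and peaks called with MACS 1.4 on the mm9 build, in so far as the submitters' processing notes name these tools and this build. The peak score in the deposited lists is the authors' own value from the peak caller. It ran from 50 to a ceiling near 3100, with a highest value of 3233, and many peaks shared the ceiling. The score was used to rank or filter peaks within a list. The start and end positions of the deposited lists are other values that the authors' peak calling set, library by library. Peaks were called in each library separately, since each list has its own numbering and its own peak borders. Read depth and the input library are not given in the sources used here, so the depth is unknown and no depth correction was made. A list that is longer, or whose peaks are wider, can come from deeper sequencing or better enrichment as well as from a difference in the cells, and a weak region just below the threshold is absent from a list without being free of signal. In wide marks the caller also left gaps: some regions with scores at the ceiling in a pair of libraries lay next to peaks of the libraries that lacked them, at times under 100 bp away.

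Overlap means at least 1 bp shared. For each antibody the peaks of the 4 libraries were merged where they overlapped and each merged region was classed by which libraries held a peak in it. With 1 library in each group there is no spread between replicates, no test was run and no p-value is given. As a scale for calling noise, the regions held by both shWdr82 libraries alone, or by both control libraries alone, were set beside the 2 crossed patterns, namely control untreated with shWdr82 LPS, and control LPS with shWdr82 untreated. These crossed patterns follow no factor of the design. Shares carry exact (Clopper-Pearson) 95% binomial intervals. Differences of shares at the same regions carry a 95% Wald interval for paired shares. All of these intervals cover counting error only and say nothing of the spread between cultures. Widths were compared for peaks that overlapped 1 to 1, as the log2 ratio of the widths, with the standard deviation (SD) of the median over the 20 chromosomes as a description of its evenness.

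Enhancer-like regions were the H3K4me1 peaks of the scrambled untreated library that overlapped an H3K27ac peak of the empty vector untreated library and lay at least 2500 bp from any H3K4me3 peak of any library. Promoter-like regions were the H3K4me3 peaks of the empty vector untreated library that overlapped an H3K27ac peak of the same vector and treatment. Since both sets were drawn on control libraries, a share that this choice fixes was not compared. The background for each share came from the same regions moved along their chromosome by 1 to 20 Mb in 20 steps. Peaks were put in the first class that they overlapped among promoter-like, enhancer-like and H3K36me3 regions of the scrambled untreated library, and otherwise counted as other. Flanks were the 10000 bp on either side of stretches covered in all 4 libraries of an antibody.

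The regions named by position follow a rule set before the data were examined. For each antibody, and for knockdown against control and LPS against untreated, regions held by both libraries of a side and by neither of the other were ranked by the lower of their 2 scores, and the 10 highest in each direction could be named. Ties at the score ceiling were ordered by position. Positions are on mm9, counted from 1. The gene table at hand uses another build (GRCm38), so no gene name was joined to any position and coordinates were not converted. The 10 gene lists, the classes based on annotated genes and the windows after gene ends were therefore not analysed here, and neither was the Wdr82 locus, whose chromatin would not show whether the hairpin lowered the mRNA. Classes from the marks and flanks around shared stretches took their place, as laid down beforehand for this case.

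The alternatives were a score of at least 100, an overlap of at least 50% of both peaks, the same number of top-scoring peaks from each library of an antibody, merging or joining within 1000 bp, a distance of 5000 bp from H3K4me3, and a flank of 5000 bp. Regions at least 10000 bp from any peak of the libraries that lack them, region sets drawn on libraries of both vectors, and the flanks of H3K4me3, H3K27ac and H3K4me1 were added after seeing the data. Computation used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. The pattern counts and width ratios were tested on simulated lists built from each antibody's own regions (13220 for H3K36me3 to 41696 for H3K4me1), where the largest error of a pattern count was 0% for each antibody. The simulated regions were set apart and held an unsplit peak in each library assigned to them. The simulation therefore checks the interval code alone, and does not cover gaps or split peaks. The overlap counts and lengths were checked against bedtools 2.31.1 in 48 comparisons, of which 0 differed.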

Results

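The 24 ChIP-seq peak lists held 756484 peaks in all, from 14420 in the Ser2P Pol II scrambled LPS library to 65149 in the H3K4me1 scrambled LPS library. They describe promoter marking (H3K4me3), marking of active promoters and enhancers (H3K27ac), enhancer priming (H3K4me1), the mark left by elongating polymerase over transcribed units (H3K36me3), total Pol II, and elongating Pol II (Ser2P) in macrophages with a Wdr82 hairpin or a control vector, untreated or with LPS. The series title speaks of early termination restraining transcription of cis-regulatory elements, so the comparison at issue is whether marks of transcription at enhancers and promoters differ when Wdr82 is depleted. Each group had 1 library and read depth is unknown. No difference below has a replicate check, and all intervals cover counting error only.

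Elongating Pol II was called over more DNA in shWdr82 cells after LPS. Ser2P peaks covered 60.6 Mb in the shWdr82 LPS library against 44.7 Mb in the scrambled LPS library, a difference of 35.5%, although the numbers of peaks were close (14870 and 14420). The median Ser2P peak was 2496 bp wide in the former and 1812 bp in the latter. In untreated cells the order was the opposite, with 43.0 Mb in shWdr82 and 46.0 Mb in scrambled cells. H3K36me3 covered the most DNA of the 6 antibodies, 234 Mb in shWdr82 and 239 Mb in scrambled untreated cells, and 234 Mb and 221 Mb after LPS. Total Pol II covered 106 Mb in shWdr82 and 112 Mb in scrambled untreated cells, and 94.2 Mb and 89.2 Mb after LPS. H3K4me3 covered 26.8 Mb in shWdr82 and 32.1 Mb in empty vector untreated cells, a difference of -16.7%, and 29.6 Mb and 29.5 Mb after 4 h of LPS.

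At enhancer-like regions, Ser2P peaks were more frequent in shWdr82 cells after LPS. Of 15511 such regions, 10.1% (95% interval 9.64 to 10.6) overlapped a Ser2P peak in the shWdr82 LPS library and 6.43% (6.05 to 6.83) in the scrambled LPS library. The difference was 3.67 percentage points (3.28 to 4.07), and 784 regions had a Ser2P peak in the shWdr82 list alone against 214 in the scrambled list alone. The share was higher in the shWdr82 library on 20 of 20 chromosomes. In untreated cells the shares were 6.34% and 5.78%, a difference of 0.561 points (0.257 to 0.864), higher in shWdr82 on 14 chromosomes. At the same regions moved along the chromosome, the median Ser2P share after LPS was 3.68% for shWdr82 and 3.08% for scrambled cells. When the shWdr82 LPS list was reduced to the top-scoring peaks that add up to the covered length of the scrambled list, its share was 6.62% (6.23 to 7.02), inside the scrambled interval. That reduced list held 6650 peaks against 14420 in the scrambled list, whose own 6650 top-scoring peaks overlapped 4.35%. When all 14870 peaks of the shWdr82 LPS list were instead narrowed about their centres to the same covered length, the share was 9.40% (8.94 to 9.87). Genes were not filtered out of the enhancer-like regions, and 25.8% of them overlapped an H3K36me3 peak in scrambled untreated cells. Ser2P there may belong to a transcribed unit that spans the region. The Ser2P shares were not split by H3K36me3.

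Total Pol II at enhancer-like regions went in opposite directions in the 2 treatments. It overlapped 21.5% of these regions in shWdr82 and 25.4% in scrambled untreated cells, a difference of -3.85 points (-4.39 to -3.31), and 19.9% against 18.0% after LPS, a difference of 1.96 points (1.46 to 2.46). With the same number of peaks per library the untreated difference was -0.969 points. The LPS minus untreated difference in the total Pol II share was -7.42 points in scrambled cells and -1.61 points in shWdr82 cells. H3K36me3 overlapped 25.8% of enhancer-like regions in both untreated libraries, and 25.5% in shWdr82 against 24.5% in scrambled cells after LPS. That last difference of 0.961 points (0.556 to 1.37) became -0.439 points with the same number of peaks per library, and the untreated difference became 1.16 points.

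**Figure D1:**
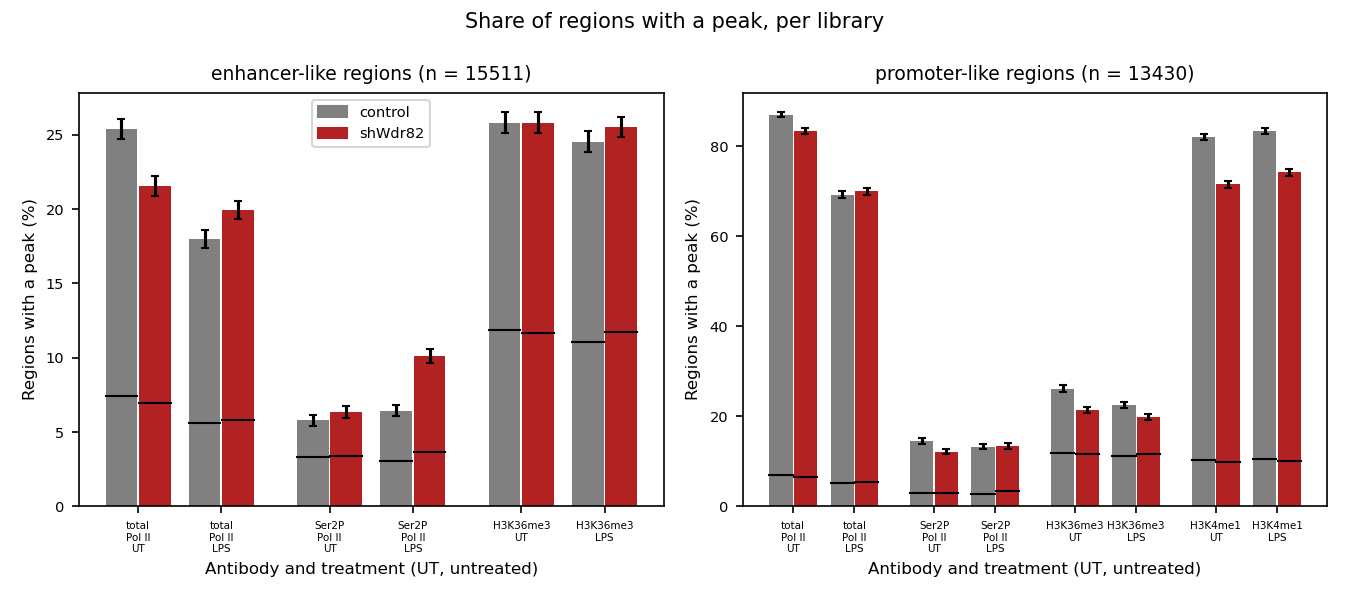
Percent of enhancer-like (left) and promoter-like (right) regions that overlap a peak, for each antibody and treatment, in control (grey) and shWdr82 (red) libraries, 1 library per bar, with exact 95% binomial intervals that cover counting error only. Black lines are the median shares at the same regions moved by 1 to 20 Mb; at enhancer-like regions the Ser2P Pol II bar after LPS stands at 10.1% in shWdr82 against 6.43% in control.

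At promoter-like regions, H3K4me1 peaks were less frequent in both shWdr82 libraries. Of 13430 regions, 71.5% (70.7 to 72.2) overlapped an H3K4me1 peak in shWdr82 and 82.1% (81.4 to 82.7) in scrambled untreated cells, a difference of -10.6 points (-11.3 to -9.90). After LPS the shares were 74.2% and 83.3%, a difference of -9.10 points (-9.76 to -8.43). The share was higher in shWdr82 on 0 of 20 chromosomes in either treatment. Both shWdr82 H3K4me1 lists held a smaller part of high-scoring peaks than the scrambled lists, as given among the results for a closer look. The length of these regions covered by H3K4me1 peaks differed less, at 46.2% in shWdr82 and 47.6% in scrambled untreated cells, and 49.8% and 50.9% after LPS. H3K36me3 peaks also overlapped fewer promoter-like regions in shWdr82 cells, 21.3% against 26.1% untreated and 19.9% against 22.5% after LPS. Total Pol II overlapped 83.3% in shWdr82 and 86.9% in scrambled untreated cells, a difference of -3.67 points (-4.16 to -3.18), and 70.0% against 69.2% after LPS, a difference of 0.812 points (0.291 to 1.33). With the same number of peaks per library these were -2.05 points untreated and 0.319 after LPS, and with a score of at least 100 the difference after LPS was 1.75 points. For Ser2P the shares were 12.1% and 14.5% untreated, and 13.4% and 13.2% after LPS, where the difference of 0.179 points (-0.280 to 0.638) was within counting error.

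A larger part of Pol II peaks was classed as enhancer-like or other in shWdr82 cells after LPS. This part is called away from promoter-like and H3K36me3 regions, but its enhancer-like peaks can also overlap an H3K36me3 region. That part was 29.2% (28.6 to 29.8) of total Pol II peaks in the shWdr82 LPS library and 24.6% (24.1 to 25.2) in the scrambled LPS library, against 23.9% and 24.8% in untreated cells. With the same number of peaks per library the order in untreated cells turned for total Pol II. For Ser2P the part was 53.7% (52.9 to 54.5) and 46.4% (45.6 to 47.2) after LPS, and 51.3% and 45.1% untreated. Among Ser2P peaks with a score of at least 100 it was 47.6% and 33.3% after LPS, and 34.5% and 29.1% untreated. As a part of the covered length, Ser2P away from these classes made up 42.3% in shWdr82 and 31.1% in scrambled cells after LPS, and 34.0% and 28.2% untreated. Both classes were drawn on untreated control libraries, which can favour control peaks. For H3K4me1 the part of peaks away from them was also higher in shWdr82, at 70.8% and 66.7% untreated and 70.5% and 67.5% after LPS. It was higher for H3K4me3 too (33.0% and 27.9%, 34.2% and 29.7%), but slightly lower for H3K27ac (56.35% and 56.50%, 55.4% and 55.7%).

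Regions present in both shWdr82 libraries and in neither control library outnumbered the reverse for H3K36me3 (1552 and 942), H3K4me3 (579 and 305) and Ser2P (432 and 391). The reverse held for H3K4me1 (2512 and 3542), total Pol II (371 and 484) and H3K27ac (153 and 181). The crossed patterns, which follow no factor, held 546 and 322 regions for H3K36me3, 157 and 59 for H3K4me3, 255 and 151 for Ser2P, 1061 and 1142 for H3K4me1, 295 and 255 for total Pol II, and 39 and 78 for H3K27ac. Each knockdown count was above both crossed counts of its antibody. With the same number of top-scoring peaks per library the order turned for H3K4me3 (291 and 392), H3K27ac (166 and 144) and Ser2P (396 and 406). For H3K36me3 it stayed (1274 and 983), but the crossed counts then differed more, at 691 and 252.

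**Figure D2:**
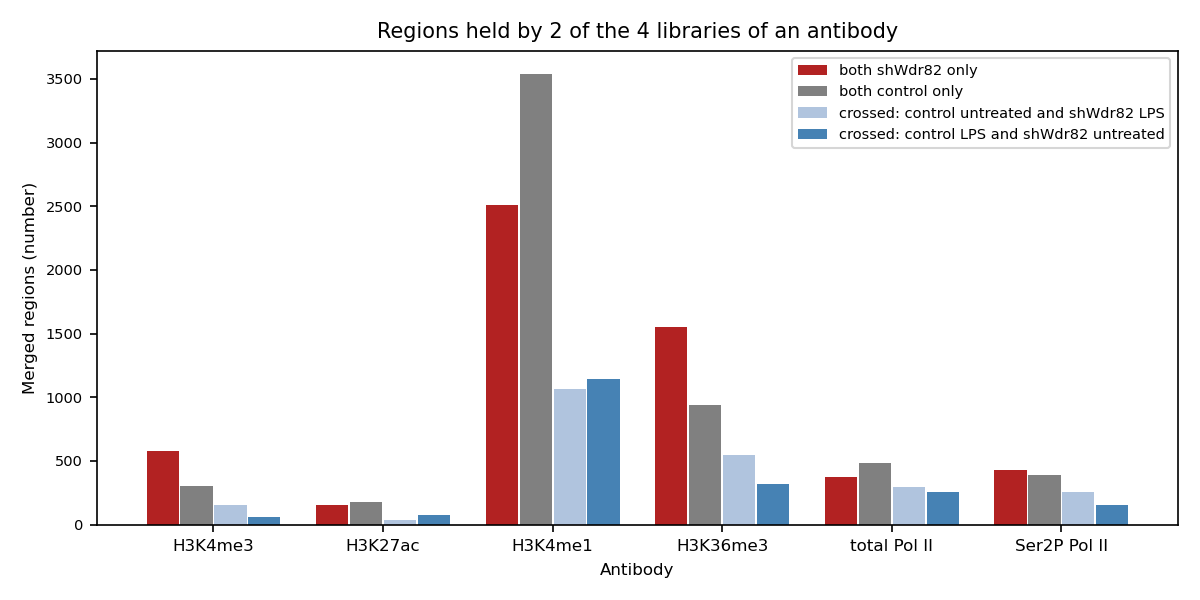
Number of merged regions (vertical axis) held by exactly 2 of the 4 libraries of each antibody (horizontal axis): both shWdr82 libraries (red), both control libraries (grey), and the 2 crossed patterns that follow no factor of the design (blue). H3K4me1 has 3542 regions in both control libraries alone and 2512 in both shWdr82 libraries alone, against 1061 and 1142 crossed.

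For Ser2P and H3K4me1, the regions held by shWdr82 libraries alone and by control libraries alone lay in different classes. Of the 432 Ser2P regions held by both shWdr82 libraries alone, 21.3% were in control H3K36me3 regions, 11.3% were enhancer-like and 59.5% were in none of the 3 classes. Of the 391 held by both scrambled libraries alone, 47.1% were in H3K36me3 regions, 4.09% were enhancer-like and 28.6% were in none. Part of that contrast was also in the crossed patterns: of the 255 regions of scrambled untreated and shWdr82 LPS cells, 32.5% were in H3K36me3 regions, 5.88% were enhancer-like and 52.9% in none, and of the 151 of scrambled LPS and shWdr82 untreated cells, 45.7%, 7.28% and 36.4%. For total Pol II the shares in shWdr82 alone and scrambled alone were close for enhancer-like (14.3% and 14.3%) and promoter-like regions (9.97% and 9.09%), and differed for H3K36me3 regions (48.5% and 62.2%, against 49.8% and 70.2% crossed). Of the 3542 H3K4me1 regions held by both scrambled libraries alone, 32.6% were promoter-like, against 6.01% of the 2512 held by both shWdr82 libraries alone and 14.9% and 13.1% of the crossed regions. H3K4me3 regions held by both empty vector libraries alone were promoter-like in 83.3% of 305 cases, but promoter-like regions were drawn on an empty vector library, so regions held by shWdr82 alone could not be counted there.

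At H3K36me3 and total Pol II regions held by shWdr82 libraries alone, Ser2P was also found more often in shWdr82 cells, as was total Pol II at such Ser2P regions. Total Pol II at the H3K36me3 regions and values at the crossed Ser2P regions are not given here. At the 1552 H3K36me3 regions of both shWdr82 libraries alone, Ser2P peaks were found at 10.4% in shWdr82 and 5.86% in scrambled untreated cells, a difference of 4.51 points (3.24 to 5.78), and at 11.2% and 7.47% after LPS, a difference of 3.74 points (2.48 to 5.00). At the crossed H3K36me3 regions the Ser2P differences lay between -1.47 and 1.47 points, each with an interval that includes 0. At the 432 Ser2P regions of both shWdr82 libraries alone, total Pol II peaks were found at 33.8% in shWdr82 and 25.9% in scrambled untreated cells, and at 35.2% and 18.1% after LPS, a difference of 17.1 points (12.8 to 21.4). At the 371 total Pol II regions of both shWdr82 libraries alone, Ser2P peaks were found at 20.8% and 13.5% untreated and 27.8% and 15.4% after LPS, a difference of 12.4 points (8.58 to 16.2). Crossed total Pol II regions held by the shWdr82 LPS library also differed in Ser2P after LPS, by 5.42 points (1.60 to 9.25). In the opposite direction, at the 391 Ser2P regions of both scrambled libraries alone, total Pol II was found at 55.0% in shWdr82 and 65.0% in scrambled untreated cells, and at 35.0% and 39.4% after LPS. At the 579 H3K4me3 regions of both shWdr82 libraries alone the differences were small and mixed in sign. In untreated and LPS cells they were 1.55 (0.164 to 2.94) and 0 points (-1.73 to 1.73) for H3K27ac, 0.173 (-2.98 to 3.33) and -2.76 (-6.11 to 0.580) for H3K4me1, -0.864 (-1.62 to -0.110) and -0.345 (-1.17 to 0.483) for H3K36me3, 0.345 (-1.45 to 2.14) and 0.864 (-0.686 to 2.41) for total Pol II, and -0.518 (-1.83 to 0.792) and 1.73 (0.3804 to 3.07) for Ser2P. At the 305 H3K4me3 regions of both empty vector libraries alone they were -8.20 (-13.0 to -3.43) and -7.21 (-11.4 to -3.03) for total Pol II, -5.90 in both treatments (-10.1 to -1.69 and -10.4 to -1.41) for H3K4me1, -4.92 (-7.81 to -2.03) and -1.31 (-4.03 to 1.41) for H3K27ac, -1.31 (-4.46 to 1.83) and 2.62 (-0.640 to 5.89) for H3K36me3, and 3.61 (0.292 to 6.92) and -0.984 (-4.44 to 2.48) for Ser2P.

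Of the 10 highest-ranked Ser2P regions of both shWdr82 libraries alone, 6 were enhancer-like, against 1 of the 10 of both scrambled libraries alone. The region at chromosome 1, 84288395 to 84299728 (mm9), an enhancer-like region of 11334 bp, lay 257106 bp from the nearest Ser2P peak of the scrambled libraries and had scores of 1314 and 962 in the untreated and LPS shWdr82 libraries, with total Pol II peaks in all 4 libraries. The first-ranked region, at chromosome 14, 26262311 to 26278023, was promoter-like and 15713 bp wide, and lay 23414 bp from the nearest scrambled peak. A further pair on chromosome 14, from 34011054 to 34023440 and from 34073142 to 34093993, was enhancer-like. The former had no H3K36me3 peak in any library, and the latter had one in all 4. Among H3K36me3 regions of both shWdr82 libraries alone, the region at chromosome 9, 7574834 to 7582795, was enhancer-like and lay 183814 bp from any H3K36me3 peak of the scrambled libraries. In contrast, the first-ranked H3K36me3 region, at chromosome 4, 14815342 to 14832925, lay 26 bp from a peak of the libraries that lacked it. The former had total Pol II peaks in both shWdr82 libraries and in neither scrambled library, and no Ser2P peak in any library. The reverse held for total Pol II at the region at chromosome X, 148314666 to 148322484. The other enhancer-like region of these 10, at chromosome 9, 65693399 to 65708177, had no total Pol II peak in any library. Of total Pol II regions of both shWdr82 libraries alone, the region at chromosome 18, 67549579 to 67570963, was promoter-like and lay 36855 bp from the nearest scrambled total Pol II peak. It had Ser2P, H3K36me3, H3K4me3 and H3K27ac peaks in all 4 libraries of each, so elongating Pol II was called there in both scrambled libraries as well. All of these positions are on mm9, and no gene was assigned to them here.

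H3K4me3 peaks were absent from individual high-scoring promoter-like regions in shWdr82 cells. The region at chromosome 2, 130908613 to 130912499, had scores of 3100 in both empty vector libraries and no H3K4me3 peak in either shWdr82 library, with the nearest such peak 19033 bp away. The regions at chromosome 6, 122871688 to 122875696, and at chromosome 19, 11407441 to 11410808, also lacked a peak in both shWdr82 libraries, with the nearest shWdr82 peak 45109 and 39453 bp away. Their scores in the untreated and LPS empty vector libraries were 2260 and 2480 for the former and 3100 and 1962 for the latter. All 3 had H3K27ac and H3K4me1 peaks in all 4 libraries of those antibodies. Total Pol II differed between them. The chromosome 19 region had total Pol II peaks in both scrambled libraries and in neither shWdr82 library. The chromosome 2 region had them in the untreated libraries of both vectors alone, and the chromosome 6 region in no library. No such high scores appeared in the other direction, where 0 of 579 regions had a lower score of at least 1000, against 10 of 305.

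Peak lists of shWdr82 and control cells shared most of their peaks for the histone marks and fewer for Pol II. Of control peaks, those overlapped by the shWdr82 list made up 90.9% for H3K4me3, 91.8% for H3K27ac, 80.3% for H3K4me1, 86.7% for H3K36me3, 75.6% for total Pol II and 57.8% for Ser2P in untreated cells. After LPS the shares were 93.2%, 86.5%, 81.2%, 89.0%, 77.6% and 63.4% in the same order. With a score of at least 100, H3K4me1 was not set apart from Pol II. Its share was then 77.2% over both treatments, against 79.2% for total Pol II and 76.9% for Ser2P. By comparison, the LPS list overlapped 69.4% of untreated peaks in empty vector cells for H3K27ac, 52.8% in scrambled cells for total Pol II and 50.1% for Ser2P. In this direction LPS separated these lists more than the hairpin did. Of LPS peaks, the untreated list overlapped 71.1%, 74.4% and 54.5%. For total Pol II and Ser2P that was close to the 74.7% and 54.5% of shWdr82 LPS peaks overlapped by the scrambled LPS list. Of the DNA covered by either list, LPS and untreated scrambled lists shared 39.2% for total Pol II and 41.8% for Ser2P. The lists of the 2 vectors shared 58.9% and 51.8% untreated, and 54.9% and 47.2% after LPS. For H3K4me1 the LPS list overlapped 87.9% of untreated scrambled peaks, more than the shWdr82 list did.

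Shared peaks differed little in width except for H3K4me3 and Ser2P. The median log2 width ratio of shWdr82 over control was -0.19 for H3K4me3 in untreated cells (SD over chromosomes 0.012, 15236 pairs) and 0.03 after LPS. For Ser2P it was -0.12 untreated (SD 0.029, 6059 pairs) and 0.13 after LPS (SD 0.036, 5243 pairs). The other 4 antibodies had medians between -0.09 and 0.06. In the 10000 bp around stretches covered in all 4 libraries, Ser2P peaks covered 20.5% of the flanks in shWdr82 and 15.5% in scrambled LPS cells, a ratio of 1.32 (SD over chromosomes 0.093), above 1 on 20 of 20 chromosomes. In untreated cells the ratio was 0.810 (SD 0.057), above 1 on 0 chromosomes. The flank ratios were 0.920 and 1.11 for H3K36me3 and 1.02 and 1.05 for total Pol II in untreated and LPS cells. With the same number of peaks per library the H3K36me3 ratios turned to 1.04 and 0.910. Differences as even over chromosomes were also seen for other marks. The ratio for H3K4me3 was 0.303 in untreated cells (SD 0.021, above 1 on 0 of 20 chromosomes) and 0.915 after LPS. For H3K27ac it was 1.23 untreated (SD 0.057, 20 chromosomes) and 0.757 after LPS (SD 0.050, 0 chromosomes), and for H3K4me1 it was 0.848 (SD 0.063, 0 chromosomes) and 0.978.

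Many H3K27ac and total Pol II regions were held by LPS libraries alone or untreated libraries alone, in both vectors and at times that were not matched. After 4 h, 4933 H3K27ac regions were present in both LPS libraries alone and 6272 in both untreated libraries alone, against 39 and 78 crossed, and the order turned to 5452 and 4761 with the same number of peaks per library. After 45 min, 1889 total Pol II regions were in both LPS libraries alone and 6541 in both untreated libraries alone (2609 and 3961 with the same number of peaks). For Ser2P the counts were 1302 and 1509, for H3K4me1 1659 and 937, for H3K36me3 269 and 540, and for H3K4me3 120 and 385. The H3K4me3 order turned to 194 and 168 with the same number of peaks, and neither H3K36me3 count exceeded the larger crossed count of 546. The smaller H3K4me1 and H3K4me3 counts also lay below their larger crossed counts of 1142 and 157. The highest-ranked H3K4me3 region gained with LPS, at chromosome 11, 83341387 to 83344156, was also gained in H3K27ac, total Pol II and Ser2P in both vectors. Total Pol II regions gained with LPS in both vectors included the enhancer-like region at chromosome 2, 129185560 to 129200569, which was also gained in Ser2P and lay 61078 bp from the nearest total Pol II peak of the untreated libraries.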

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

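Of the tests in this part, the H3K36me3 comparison at the same number of peaks was chosen only after the result was seen, the narrowing of Ser2P peaks after the shares at equal covered length were seen, and the H3K4me1 comparison within the scrambled vector after that between vectors was seen. The results listed first are those in which the shWdr82 minus control difference, as a percentage of the control value, went in opposite directions in untreated and LPS cells, by at least 5% each way. The numbers of peaks, covered lengths, widths of shared peaks and flank lengths of the 6 antibodies were searched, with the shares at the 2 region classes that the choice of regions does not fix and the parts of Pol II peaks away from promoter-like and H3K36me3 regions. With 1 library in each group the difference between treatments was not tested.

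The length covered by Ser2P Pol II peaks differed by 35.5% after LPS and by -6.57% in untreated cells. The Ser2P length in the flanks of shared stretches differed by 32.3% after LPS and by -19.0% in untreated cells, and the median of the width ratios of shared Ser2P peaks, taken pair by pair, lay 9.55% above 1 after LPS and 7.79% below 1 in untreated cells. The H3K36me3 length in such flanks differed by 11.0% after LPS and by -8.04% in untreated cells, but with the same number of peaks per library both directions turned (ratios of 0.910 and 1.04). The number of H3K36me3 peaks itself differed by 13.8% after LPS and by -8.41% in untreated cells. The length covered by total Pol II differed by 5.64% after LPS and by -5.21% in untreated cells, and its share of enhancer-like regions by 10.9% and -15.2%, where with the same number of peaks per library the untreated difference was -0.969 instead of -3.85 points. The length covered by H3K27ac differed by -9.84% after LPS and by 7.59% in untreated cells, and its length in flanks by -24.3% and 22.7%.

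The higher Ser2P share at enhancer-like regions after LPS (10.1% in shWdr82, 6.43% in scrambled cells) was weighed first. A rise by the same ratio over the whole genome is argued against. The ratio of the shares was 1.57 at these regions and at most 1.29 in 20 shifts of 1 to 20 Mb (SD 0.053). These shifts cannot test a deeper or better enriched library, which could add calls mainly where weak signal lies just below the threshold. The shWdr82 LPS list did score higher. Peaks with a score of at least 100 made up 62.7% against 53.6% in scrambled cells, and those of at least 1000 made up 17.7% against 14.5%. In untreated cells the order was reversed, at 48.8% against 53.7% and 9.99% against 13.0%. A deeper or better enriched library therefore stays open. Wider peaks at an unchanged number of peaks, as the whole cause, are argued against too, since the list with every peak narrowed to the scrambled list's covered length overlapped 9.40% (8.94 to 9.87) of the regions. The longer called length stays open in another form, because the list reduced to its top-scoring peaks of that covered length overlapped 6.62%. That reduction left 6650 peaks against 14420 in the scrambled list, so it does not show that length accounts for the difference. With the same number of top-scoring peaks per library the difference was 3.79 points. That setting kept 14420 of the 14870 peaks of the shWdr82 LPS list, so it bears little on length. A gain over the wider neighbourhood also stays open, since in 10 shifts of 20 to 100 kb the highest ratio was 1.59, though the median was 1.41 and the lowest 1.31. Depletion of Wdr82 is open beside these, and depth is unknown.

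The lower H3K4me1 share at promoter-like regions in both shWdr82 libraries was weighed second. The shWdr82 H3K4me1 lists did score lower. Peaks with a score of at least 1000 made up 4.77% in shWdr82 and 8.23% in scrambled untreated cells, and 6.17% and 8.94% after LPS. Weaker H3K4me1 enrichment overall therefore stays open as a part of the cause. As the whole cause it is argued against, since scrambled peaks at promoter-like regions were retained less often than other scrambled peaks of the same score decile, by -6.31 points untreated (SD over chromosomes 1.67) and -5.95 points after LPS (SD 1.46). H3K4me1 calls at promoter-like regions that vary between any 2 lists would also vary between the 2 scrambled lists. Scrambled peaks there were retained in the scrambled list of the other treatment more often than matched peaks. The excess was 2.32 points from the untreated list and 1.56 points from the LPS list. These values lie 8.63 (SD over chromosomes 2.05) and 7.51 points (SD 2.23) above the matched differences for the shWdr82 lists. They argue against such variation between the 2 scrambled lists. With only this pair of lists and an SD over chromosomes, they cannot show how calls vary between other libraries or cultures. Less stable calls that appear only between the vectors cannot be told apart from a difference in the cells. There shWdr82 peaks were retained more often, by 9.24 points untreated (SD 3.52) and 8.78 points after LPS (SD 2.15), but this follows largely from the lower share itself, and the comparison of sizes fixed in advance (-2.93 and -2.83 points) did not foresee opposite signs. Depletion of Wdr82 stays open beside this, with the covered length of the regions nearly equal and no second library of either group.

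The excess of H3K36me3 regions in both shWdr82 libraries alone (1552 against 942) was weighed last. At the same number of peaks per library the ratio was 1.30 (1274 and 983), below the ratio of the crossed patterns, 2.74 (691 and 252). The full lists already met that bound, with 546 and 322 crossed regions. The comparison therefore cannot decide whether different numbers of peaks per library account for the excess. For gaps inside wide stretches, the ratio among regions at least 10000 bp from peaks of the lacking libraries was 2.58 against 2.08 for the crossed patterns, and the interval of their quotient (0.814 to 1.89, counting error only) includes 1, so gaps and a difference in the cells cannot be told apart from these counts. The biological explanation, the Wdr82 hairpin, stays open.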

How the results depend on the processing

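The tests on regions at least 10000 bp from peaks of the lacking libraries, on region sets drawn on libraries of both vectors, and on the flanks of H3K4me3, H3K27ac and H3K4me1 were chosen only after the result was seen, and the others before the data were examined. Vectors were set side by side within each treatment; an additive fit of vector and treatment over the 4 libraries of an antibody, which leaves 1 residual degree of freedom, was not run. The gene lists were not run for lack of an mm9 annotation. Depth is unknown, which limits every count of peaks. All 24 alternative width ratios lay within the SD over chromosomes of the value reported, and 20 of 24 peak counts, 21 of 24 enhancer-like differences, 11 of 24 promoter-like differences and 29 of 36 flank ratios stayed within 1.5 times or their spread. So did 23 of 48 knockdown pattern counts, where 6 turned in order, 24 of 48 LPS pattern counts, where 4 turned, 0 of 18 shares of overlapped control peaks and 1 of 16 parts of Pol II peaks away from promoter-like and H3K36me3 regions. The higher Ser2P share at enhancer-like regions in the shWdr82 LPS library stayed within its spread under each of the 4 alternatives, which do not set the covered lengths equal. At the covered length of the scrambled list, a test given among the results for a closer look, the share was 6.62% with fewer peaks and 9.40% with narrowed peaks. Where a result moved or turned, the cause was not tested, except that stricter rules leave fewer peaks or regions by construction.

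With a score of at least 100 the Ser2P lists kept 8407 (scrambled untreated), 7723 (scrambled LPS 45 min), 8172 (shWdr82 untreated) and 9328 (shWdr82 LPS 45 min) peaks. The shWdr82 lists overlapped 85.9% (H3K4me3), 79.7% (H3K27ac), 73.3% (H3K4me1), 70.1% (H3K36me3), 57.7% (total Pol II) and 40.3% (Ser2P Pol II) of control peaks with at least 50% of both peaks shared. The shWdr82 lists overlapped 94.3% (H3K4me3), 90.7% (H3K27ac), 77.2% (H3K4me1), 88.3% (H3K36me3), 79.2% (total Pol II) and 76.9% (Ser2P Pol II) of control peaks with a score of at least 100. The shWdr82 lists overlapped 91.1% (H3K4me3), 90.3% (H3K27ac), 81.9% (H3K4me1), 87.0% (H3K36me3), 79.7% (total Pol II) and 61.7% (Ser2P Pol II) of control peaks with the same number of peaks per library.

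With a score of at least 100, knockdown patterns held 227 in both shWdr82 (total Pol II) and 228 in both shWdr82 and 216 in both control (Ser2P Pol II) libraries alone. With the same number of peaks per library, knockdown patterns held 291 in both shWdr82 and 392 in both control (H3K4me3), 166 in both shWdr82 and 144 in both control (H3K27ac) and 396 in both shWdr82 and 406 in both control (Ser2P Pol II) libraries alone, and the order turned for H3K4me3, H3K27ac and Ser2P Pol II. With merging within 1000 bp, knockdown patterns held 203 in both control (H3K4me3), 921 in both shWdr82 and 603 in both control (H3K36me3) and 208 in both shWdr82 and 280 in both control (total Pol II) libraries alone. Among regions at least 10000 bp from peaks of the lacking libraries, knockdown patterns held 132 in both control (H3K4me3), 61 in both shWdr82 and 75 in both control (H3K27ac), 754 in both shWdr82 and 918 in both control (H3K4me1), 553 in both shWdr82 and 214 in both control (H3K36me3), 91 in both shWdr82 and 100 in both control (total Pol II) and 182 in both shWdr82 and 146 in both control (Ser2P Pol II) libraries alone.

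With a score of at least 100, LPS patterns held 66 in both LPS and 223 in both untreated (H3K4me3) and 590 in both untreated (H3K4me1) libraries alone. With the same number of peaks per library, LPS patterns held 194 in both LPS and 168 in both untreated (H3K4me3), 5452 in both LPS and 4761 in both untreated (H3K27ac) and 3961 in both untreated (total Pol II) libraries alone, and the order turned for H3K4me3 and H3K27ac. With merging within 1000 bp, LPS patterns held 140 in both LPS and 251 in both untreated (H3K36me3), 1178 in both LPS (total Pol II) and 823 in both LPS (Ser2P Pol II) libraries alone. Among regions at least 10000 bp from peaks of the lacking libraries, LPS patterns held 65 in both LPS and 243 in both untreated (H3K4me3), 2991 in both LPS and 3433 in both untreated (H3K27ac), 437 in both LPS and 288 in both untreated (H3K4me1), 43 in both LPS and 72 in both untreated (H3K36me3), 954 in both LPS and 3964 in both untreated (total Pol II) and 692 in both LPS and 994 in both untreated (Ser2P Pol II) libraries alone.

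At enhancer-like regions, shWdr82 minus control was -0.969 (total Pol II, untreated), 1.16 (H3K36me3, untreated) and -0.439 (H3K36me3, LPS 45 min) points with the same number of peaks per library. At promoter-like regions, shWdr82 minus control was -14.6 (H3K4me1, untreated), -12.5 (H3K4me1, LPS 45 min) and 1.75 (total Pol II, LPS 45 min) points with a score of at least 100. At promoter-like regions, shWdr82 minus control was -11.6 (H3K4me1, untreated), -9.84 (H3K4me1, LPS 45 min), -5.64 (H3K36me3, untreated), -3.28 (H3K36me3, LPS 45 min), -2.95 (total Pol II, untreated), 1.35 (total Pol II, LPS 45 min) and -0.373 (Ser2P Pol II, LPS 45 min) points with regions drawn on libraries of both vectors. At promoter-like regions, shWdr82 minus control was -7.74 (H3K4me1, LPS 45 min), -3.65 (H3K36me3, LPS 45 min) and -2.05 (total Pol II, untreated) points with the same number of peaks per library. The H3K36me3 difference after LPS at enhancer-like regions turned with the same number of peaks per library; that of Ser2P after LPS at promoter-like regions, within counting error as reported, turned with regions drawn on libraries of both vectors. Outside promoter-like and H3K36me3 regions lay, with a score of at least 100, 24.3% (total Pol II scrambled untreated), 23.4% (total Pol II scrambled LPS 45 min), 22.9% (total Pol II shWdr82 untreated), 26.8% (total Pol II shWdr82 LPS 45 min), 29.1% (Ser2P Pol II scrambled untreated), 33.3% (Ser2P Pol II scrambled LPS 45 min), 34.5% (Ser2P Pol II shWdr82 untreated) and 47.6% (Ser2P Pol II shWdr82 LPS 45 min) of peaks. Outside promoter-like and H3K36me3 regions lay, with the same number of peaks per library, 22.3% (total Pol II scrambled untreated), 25.8% (total Pol II scrambled LPS 45 min), 22.5% (total Pol II shWdr82 untreated), 30.2% (total Pol II shWdr82 LPS 45 min), 43.5% (Ser2P Pol II scrambled untreated), 47.3% (Ser2P Pol II scrambled LPS 45 min) and 48.0% (Ser2P Pol II shWdr82 untreated) of peaks. Thereby the order of the untreated total Pol II parts turned, from lower to slightly higher in shWdr82 than in scrambled cells. The flank ratio was 1.06 (total Pol II, untreated) with a flank of 5000 bp. The flank ratio was 0.282 (H3K4me3, untreated) with a score of at least 100. The flank ratio was 1.04 (H3K36me3, untreated), 0.910 (H3K36me3, LPS 45 min), 1.10 (total Pol II, untreated), 0.266 (H3K4me3, untreated) and 1.04 (H3K4me1, LPS 45 min) with the same number of peaks per library. Thereby both H3K36me3 flank ratios turned, and that of H3K4me1 after LPS passed 1.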

Other observations

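H3K27ac regions that came or went with 4 h of LPS in both vectors differed in their H3K4me1. Of 4206 regions present in both LPS libraries alone and at least 2500 bp from H3K4me3, 38.1% (36.6 to 39.6) had an H3K4me1 peak in scrambled untreated cells and 38.3% in shWdr82 untreated cells. Of 4582 such regions present in both untreated libraries alone, 87.6% (86.7 to 88.6) and 84.9% did. Of 6630 regions present in all 4 H3K27ac libraries, the shares were 94.1% and 92.3%. At 45 min of LPS, an earlier time than that of H3K27ac, 41.3% of the regions of the LPS libraries had an H3K4me1 peak in scrambled cells and 41.7% in shWdr82 cells.

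Total Pol II, measured at 45 min of LPS against 4 h for H3K27ac, was found more often after LPS at regions of the LPS libraries and less often at the other 2 classes. The total Pol II lists held fewer peaks after LPS, 21891 against 32385 in scrambled and 22307 against 28497 in shWdr82 cells. Shorter lists can lower the share at any set of regions. At regions present in both untreated H3K27ac libraries alone, total Pol II was found at 15.9% in untreated and 6.94% in LPS scrambled cells, and at 13.3% and 8.27% in shWdr82 cells. At regions present in both LPS libraries alone it was found at 9.22% and 10.6% in scrambled cells, and at 8.13% and 12.6% in shWdr82 cells. At regions of all 4 libraries it was found at 34.7% in untreated and 25.6% in LPS scrambled cells, and at 29.6% and 27.6% in shWdr82 cells, so a lower share after LPS was not particular to the regions that lost H3K27ac. At those regions Ser2P went from 5.67% to 5.11% with LPS in scrambled cells and from 5.89% to 6.79% in shWdr82 cells. Ser2P after LPS was higher in the shWdr82 library in all 3 classes, at 8.94% against 6.06% for regions of the LPS libraries, 6.79% against 5.11% for regions of the untreated libraries, and 12.4% against 7.71% for regions of all 4 libraries. The Ser2P list of the shWdr82 LPS library covered more DNA, as given for the enhancer-like regions, and the same limit holds here.

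H3K4me3 regions of both shWdr82 libraries alone were narrow, as were those of most other pairs of libraries. Their median width was 688 bp, against 1168 bp for those of both empty vector libraries alone and 1910 bp for regions of all 4 libraries, but the crossed regions had medians of 686 and 509 bp, and those of both LPS and both untreated libraries alone 702 and 725 bp. Of the 579, 387 lay at least 10000 bp from any H3K4me3 peak of the empty vector libraries, and of the crossed regions 100 of 157 and 40 of 59 lay as far from peaks of the libraries that lacked them. The region at chromosome 7, 53651438 to 53652347, lay 241882 bp from such a peak and had no peak of any other antibody.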
